A study of Gallus gallus with 14 samples.

How the data were processed

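Gene expression was measured in the cerebral cortex of chicken embryos on 2-colour Agilent arrays in the 4x44k format, 1 array per biological replicate per the labels. The groups came from the labels: the solvent DMSO (5 arrays), perfluorohexane sulfonate (PFHxS) at 890 ng/g (low dose, 4 arrays) and PFHxS at 38000 ng/g (high dose, 5 arrays). Per the labels, eggs were kept at 37.5 degrees Celsius and 57% humidity, received a single injection into the air cell, and cortex was taken at day 21 to 22. Total RNA was isolated with RNeasy kits and labelled with Quick Amp kits, per the labels' protocols. Every array carried the embryo RNA in Cy5 and a common pool in Cy3, to which each control and treated sample gave the same share. No dyes were swapped, so a dye effect is shared by all groups.

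Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1 on a design made from the galGal3 genome build. The deposited intensity columns used here hold the median pixel signal of each spot and the median local background in each channel. The design fixed beforehand named the mean signal, which these columns do not hold, and the median signal took its place. The deposited log10 ratios (log10 of Cy5 over Cy3, from signals that the software had background-subtracted and dye-normalised, per the file headers) served as an alternative. The series matrix, also in log10 units and deposited by the authors, correlated at 1 with these ratios on every array over 43553 probes, and its column medians were 0 on 13 arrays and 0.0858 on LD 2. It thus has the direction embryo over pool.

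The analysis used R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8). Signals were corrected with normexp (offset 50) and normalised by loess within each array with control spots at weight 0. Spots marked as non-uniform or population outliers were left out (3 to 1280 per array), and spots of 1 probe were averaged. Of 43603 probes, 30294 were kept because their Cy5 signal was well above background on at least 4 arrays. Accessions in the files matched a gene symbol for 10425 probes through a list of RefSeq genes (assembly GRCg7b), of which 8509 were kept, for 4222 symbols. Probe coordinates are on another build and are not given. A probe without a symbol is unnamed here.

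One model with a mean per group was fitted to all 14 arrays, and limma's moderated test was two-sided with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The comparisons were high dose against DMSO, low dose against DMSO, high dose against low dose, and a moderated F test over the groups. Of 29 gene lists on brain cell types, metabolism and stress, 28 had at least 5 measured genes and were tested with camera in limma, using 1 probe for each gene (the one of highest mean signal), over 4001 genes with a value on every array. Camera asks whether a list lies above or below the other genes, with a preset correlation of 0.01 between genes, and it was repeated with an estimated correlation. Fry asks another question, whether a list differs from no change, and was run beside it. Beside each list, the members passing were also counted adjusted over the list alone. The list of W chromosome genes held only HINTW and was used as a measure per array.

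The rule for named genes took the 12 genes of largest change per direction among those past the threshold (6 for high dose against low dose), and filled each direction up to 6 genes with the smallest unadjusted p where fewer passed. It added up to 4 members of each list described, and DIO2, DIO3, NRGN, THRB, TTR, MBP and POU2F1. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives covered background correction, normalisation, the Cy5 channel alone, the deposited series matrix, the filter, outlier spots, moderation, array weights, blocks for slide and for replicate number, HINTW as a covariate, and leaving out each array. Alternatives that left out the 3 arrays with low spike-in slopes, or LD 2 together with a slide block, or kept outlier spots in the list tests, were added after seeing the data.

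The probe test was tried on simulated data for 28898 probes. The values were independent random noise with each real probe's SD and each array's relative spread. For high dose against DMSO the test recovered 32% of probes changed 1.5-fold, 58% changed 2-fold, 86% changed 3-fold and 98% changed 4-fold. The shares were 16%, 70%, 84% and 96% for low dose against DMSO, and 24%, 76%, 82% and 92% for high dose against low dose. Among unchanged probes, 2, 9 and 10 were called in the 3 comparisons. The list test found a blood list raised by 0.3 log2 in high dose against DMSO in 20 of 20 runs over 4001 genes. It made 3 calls of other lists. Genes were uncorrelated in these runs, whereas the correlation estimated in the data was 0.11 for the blood list and 0.199 for cell cycle. The runs thus do not cover correlated genes. The number of arrays limits the precision: the median 95% half-width of a log2 change was 0.40 for high dose against DMSO and 0.42 for both comparisons with the low dose. Across 91 pairs of arrays no files held identical values.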

Results

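The data describe how messenger RNA levels in the cerebral cortex of chicken embryos differed after exposure to PFHxS, a perfluorinated surfactant, at 890 ng/g (LD, n = 4) or 38000 ng/g (HD, n = 5), against the solvent DMSO (n = 5). Each value is a log2 ratio of an embryo's signal to that of a common pool on the same array. On 13 arrays, 20673 to 34738 probes were well above background in the embryo channel, and on LD 2 there were 41505. The arrays lay on 4 slides, each of which held all 3 groups.

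HINTW, a gene of the W chromosome that only female birds carry, differed widely between arrays of the same group. Its mean log2 ratio over 7 probes was 0.40 to 1.02 on DMSO 1, DMSO 2 and DMSO 3, 0.42 on HD 1, 0.86 on HD 3, 0.42 on HD 4 and -0.05 on LD 2. It was -4.73 on DMSO 4, -4.00 on LD 1, -4.65 on LD 3, -4.39 on LD 4 and -4.35 on HD 2, and lay between these at -1.50 on DMSO 5 and -1.18 on HD 5. HINTW was thus at -4.00 or below on 3 of 4 LD arrays, 1 of 5 DMSO arrays and 1 of 5 HD arrays. DMSO 5 and HD 5, where spike-in ratios were also pulled towards 0, and LD 2, of poor quality, were not assigned a sex. By HINTW on the other arrays the groups did not hold the sexes equally, and a difference of the low dose from either other group is mixed with sex. As a covariate, HINTW entered with its values as they stood on all arrays. Among the LD arrays it set LD 2 apart, so a fit with it can also take up what was unlike on LD 2. Transthyretin (TTR), a carrier of thyroid hormone made by the choroid plexus, was at 3.89 on HD 2, at -1.36 on DMSO 5 and -1.34 on HD 5, and from -5.74 to -3.81 on the others.

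**Figure D1:**
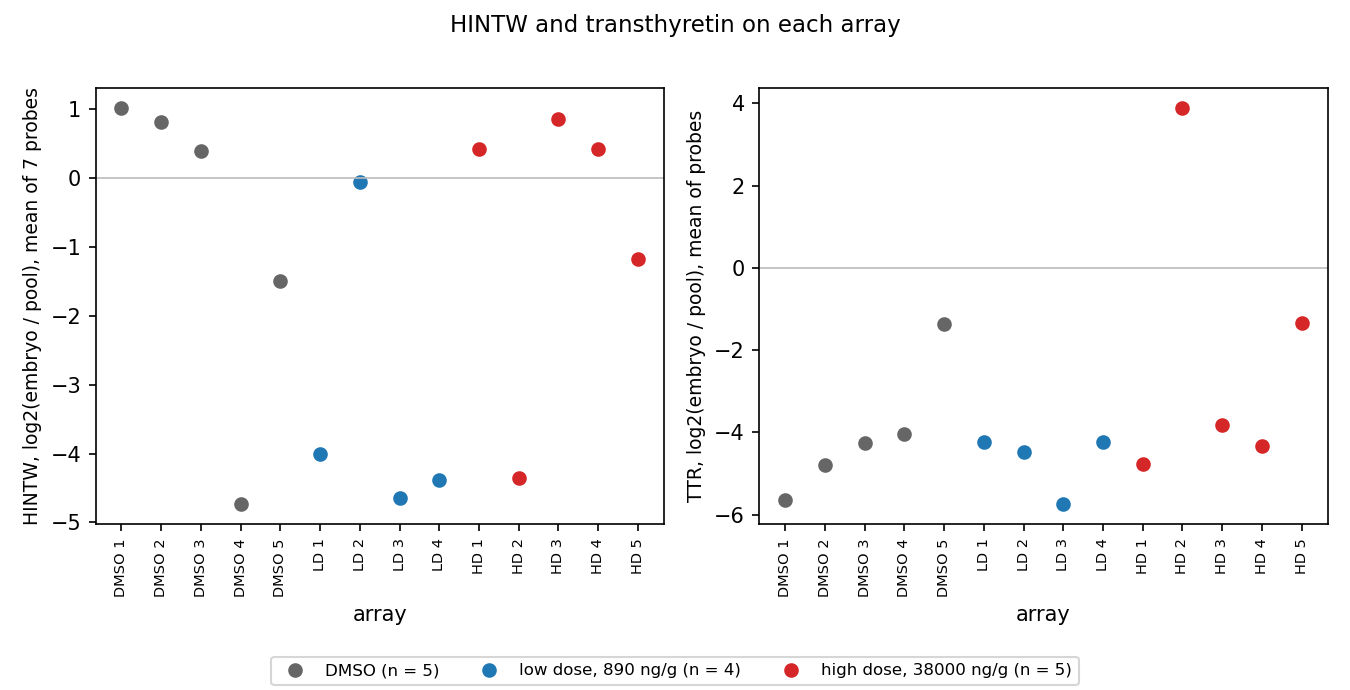
Each point is 1 array, with the log2 ratio of embryo to pool on the vertical axis for HINTW (left, mean of 7 probes) and TTR (right, mean of its probes), coloured by group. HINTW spans -4.73 to 1.02, and TTR is at 3.89 on HD 2 and below 0 on every other array.

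Array quality was uneven. The SD of log2 ratios over probes was 0.913 on LD 2 and 0.248 to 0.461 on the other arrays. The slope of observed on expected log ratios of the spike-in RNAs, as given by the scanner software, was 0.577 on DMSO 5, 0.646 on LD 2 and 0.529 on HD 5, against 0.901 to 0.940 on the other 11 arrays. The pool signals of LD 2 had a median Spearman correlation of 0.795 with those of other arrays, where the remaining arrays had at least 0.955.

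**Figure D2:**
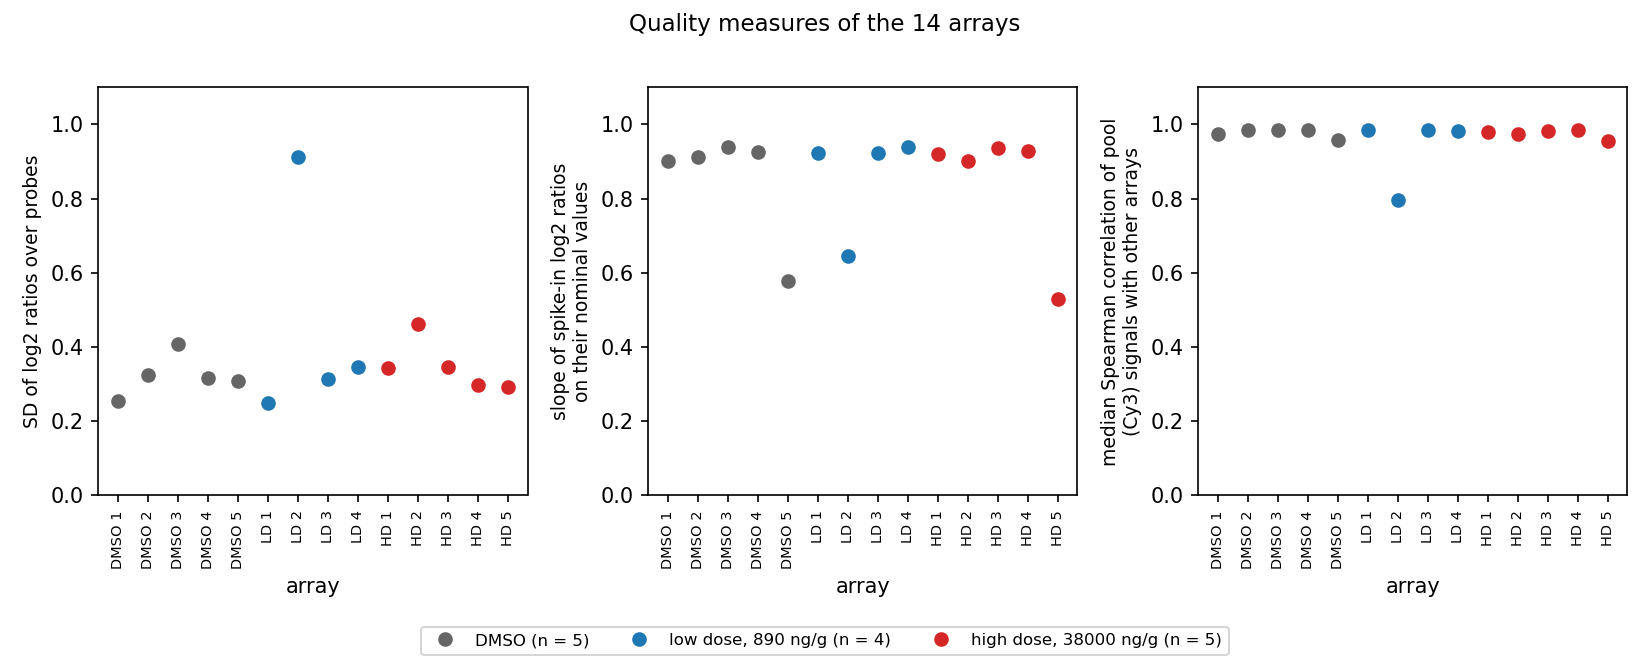
Each point is 1 array, coloured by group; the panels show the SD of log2 ratios over probes, the slope of the spike-in log ratios and the median Spearman correlation of the pool (Cy3) signals with those of other arrays. LD 2 stands apart in all panels, and DMSO 5 and HD 5 in the spike-in slope.

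The high dose was set against DMSO to ask which cortical genes responded to PFHxS. Genes of blood and red cells rose as a list: its 11 measured genes had a median log2 change of 0.29, with 7 above 0 and 4 below (limma's camera, adjusted p = 0.00342). The call was lost with an estimated correlation (adjusted p = 0.497 with an estimated correlation), and fry, which tests against no change and not against other genes, made no call (adjusted p = 0.991). The globins, the oxygen carriers of red cells, had the largest values. The embryonic β-type globin HBE was at -0.21 ± 0.42 (SD, n = 5) in DMSO and 0.57 ± 0.58 (n = 5) at the high dose, a difference of 0.78 ± 0.27 (SE) or 1.72-fold. HBE was at 1.34 on HD 2 and 1.04 on HD 3. On the other HD arrays it was at 0.03 to 0.25, within the range of the DMSO arrays (-0.62 to 0.40). Within slides, with 1 or 2 arrays per group, the high dose lay above DMSO in HBE by 0.13, 0.94, 1.4 and 0.83. With slide as a block the change of HBE was 0.86 (limma, unadjusted p = 0.00052) and did not pass either. HBBA differed by 0.83 ± 0.31 at its brightest probe, and the α-type globins HBA1 and HBAD by 0.53 ± 0.23 and 0.45 ± 0.25.

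None of the 11 members passed the test adjusted over the list alone, where the smallest adjusted p from limma was 0.0933, and none passed over all probes. The transcription factor TAL1 was at -0.05, LMO2 at 0.08 and FECH, the last enzyme of haem synthesis, at -0.02. The mean of the list was 0.12, 0.32, 0.30, -0.02 and -0.01 on the HD arrays, and from -0.35 to 0.02 on the DMSO arrays. Within slides the difference was 0.22, 0.30, 0.52 and 0.12, and with slide as a block the median was 0.29 (camera, adjusted p = 0.000272). The call was lost without DMSO 3 (median 0.249, adjusted p = 0.0616) and without DMSO 4 (0.151, adjusted p = 0.108), and the median was 0.158 without HD 3; over 32 alternatives the adjusted p ranged from 2.35e-05 to 0.991. The median was also lower with each array centred on its median in place of loess (0.07) and with the mean of all probes per gene (0.16).

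**Figure D3:**
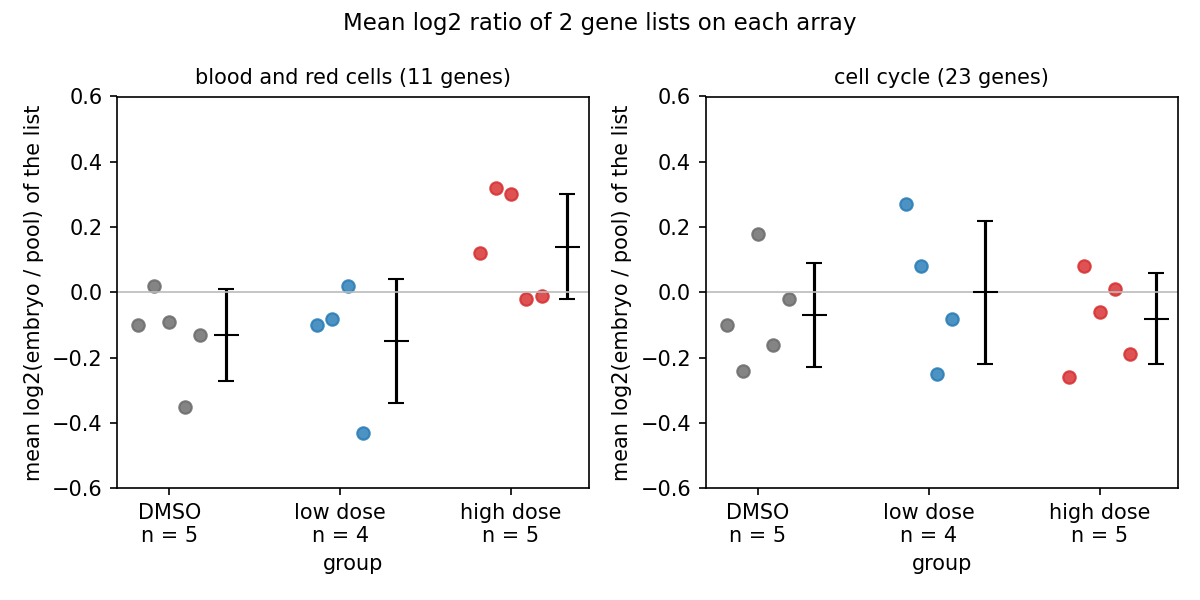
Each point is the mean log2 ratio of a list on 1 array, for blood and red cells (left, 11 genes) and cell cycle (right, 23 genes); bars show the group mean ± SD. The blood list lies at -0.13 ± 0.14 in DMSO, -0.15 ± 0.19 at the low dose and 0.14 ± 0.16 at the high dose.

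No single probe passed for the high dose. limma called 0 of 30294 probes (smallest adjusted p = 1). With no change, a share of about 0.05 of the probes would have an unadjusted p under 0.05. Here 324 (1.07%) did, of which 167 were higher and 157 lower. This count was 174 without DMSO 5, 493 without DMSO 2, 743 without DMSO 3, 730 without LD 2 and 556 without HD 1, and 698 with slide as a block. LD 2 was in neither of the groups compared, but it entered the estimate of spread that all groups shared. The genes below are those with the smallest unadjusted p, given as values that did not pass. On the higher side were HBE, HBBA (0.68 ± 0.23 at this probe), the red cell membrane protein RHAG (0.43 ± 0.15), FAAHL (0.50 ± 0.17), NMRAL1 (0.45 ± 0.15) and CDIN1 (0.33 ± 0.11). RHAG was well above background on 1 of 5 DMSO arrays, 3 of 4 LD arrays and 5 of 5 HD arrays, FAP on 4, 2 and 2, and SPATA7 on 4, 4 and 2. FAAHL, related to fatty acid amide hydrolase, was at 0.32 to 0.46 on the HD arrays and -0.79 to 0.20 on the DMSO arrays; without DMSO 5, the array at -0.79, FAAHL, high dose against DMSO, was at 0.325. On the lower side were the splicing factor SRSF11 (-0.54 ± 0.17), the lysophosphatidic acid receptor LPAR2 (-0.48 ± 0.18), the adhesion adaptor LIMS1 (-0.37 ± 0.12), the serotonin receptor gene HTR7L (-0.36 ± 0.13), the serine protease FAP (-0.28 ± 0.10) and SPATA7 (-0.28 ± 0.10). Other probes of CDIN1 (1 of 2), NMRAL1 (1 of 1), SRSF11 (1 of 3) and FAP (1 of 1) had the opposite sign.

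Thyroid hormone genes were examined because perfluorinated compounds are known to bind thyroid hormone carriers. The list had a median of -0.04 and a mean of 0.30 over 11 genes, and camera placed it above other genes (adjusted p = 0.74). MBP, a myelin protein induced by thyroid hormone, was at -1.34 ± 0.56 in DMSO, -0.47 ± 1.34 at the low dose and -0.29 ± 0.64 at the high dose (SD), with LD 4 at 1.46. Its log2 change was 1.05 ± 0.49 (SE) at the high dose and 0.87 ± 0.52 at the low dose, and did not pass (limma, adjusted p = 1 and 0.85). Without LD 4, MBP, low dose against DMSO, was at 0.225. DIO2, which activates thyroid hormone, had 0.46 ± 0.26 at the high dose and 0.00 ± 0.27 at the low dose, and DIO3, which inactivates it, -0.36 ± 0.35 and -0.17 ± 0.37. These rested on single arrays: DIO2, high dose against DMSO, was at 0.244 without HD 1 (1.23), and without DMSO 4 (1.52) DIO3, high dose against DMSO, was at -0.0145 and DIO3, low dose against DMSO, at 0.174. TTR had 1.91 ± 1.35 at the high dose, with HD 2 alone above 0; without HD 2, TTR, high dose against DMSO, was at 0.42. POU2F1 had -0.07 ± 0.20. THRB had no kept probe, and no probe carried the symbol NRGN.

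Among the other lists, that of oligodendrocytes and myelin had a median of 0.13 over 13 genes (camera, adjusted p = 0.19; 0.95 with an estimated correlation). Its members included MBP, ERMN (0.22 ± 0.15), OLIG2 (0.14 ± 0.14) and CLDN11, a tight junction protein of myelin (-0.75 ± 0.60). Cholesterol synthesis had a median of 0.15 over 8 genes (adjusted p = 0.32), with LSS, which closes the sterol rings, at 0.24 ± 0.16 and INSIG1 at 0.23 ± 0.16. Oxidative phosphorylation had 0.11 over 9 genes (adjusted p = 0.27), with the complex I subunit NDUFS1 at 0.41 ± 0.22. PPAR targets and fatty acid oxidation, which perfluorinated acids raise in liver, had a median of 0.01 and a mean of -0.02 over 18 genes (adjusted p = 0.86), with HADHA at -0.46 ± 0.27 and FABP3 at -0.28 ± 0.21.

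The low dose was set against DMSO for the same question. Among the genes of smallest unadjusted p, those on the higher side were the peptide gene UTS2B (1.44 ± 0.42, 2.72-fold), the phosphatase CDC14A (1.03 ± 0.28, 2.04-fold), the cytidine deaminase CDA (0.83 ± 0.22, 1.78-fold) and NSA2, a ribosome assembly factor (0.83 ± 0.26). PDHB, a subunit of pyruvate dehydrogenase, had 0.71 ± 0.23 and the muscarinic receptor CHRM3 0.64 ± 0.20, with signal well above background on 2 of 5 DMSO, 3 of 4 LD and 1 of 5 HD arrays. UTS2B was at 2.38 on LD 2 and 1.80 on LD 3, and at 0.19 on LD 1 and -0.12 on LD 4. LD 2, an array of poor quality, also held the highest LD value of CDA (1.14, with LD 1 at -0.19), PDHB (1.05) and CHRM3 (1.02). It held the lowest LD value of PIK3R6, LPAR2 (-0.87) and DDTL (-0.36). For NSA2 it tied with LD 4 (0.79), and for CDC14A, WNT5A, WNT11, MKNK1 and FAP another LD array was more extreme. On the lower side were PIK3R6, a regulatory subunit of a phosphoinositide kinase (-1.04 ± 0.31, 0.486-fold), the Wnt ligands WNT5A (-0.80 ± 0.23) and WNT11 (-0.67 ± 0.19), DDTL (-0.67 ± 0.17), the kinase MKNK1 (-0.51 ± 0.14) and FAP (-0.35 ± 0.10). PIK3R6 was low on all the low-HINTW arrays: DMSO 4 (-0.82), HD 2 (-0.86), LD 1 (-0.59), LD 3 (-1.23) and LD 4 (-0.76). Apart from LD 2, the arrays without low HINTW had -0.17 to 0.75. PIK3R6 was lowest on LD 2 (-1.50), where HINTW was not low, but that array was unlike the others in both channels. LD 2 thus cannot decide between dose and sex. With the W probes as covariate the change of PIK3R6, low dose against DMSO, was -0.756, in a fit that includes LD 2. LPAR2, at -0.54 ± 0.19, was close to its value at the high dose. None of these passed.

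limma called 0 of 30294 probes at the low dose (smallest adjusted p = 0.85). Again fewer than expected with no change, 902 (2.98%) had an unadjusted p under 0.05, of which 338 were higher and 564 lower. There were 2656 of these without LD 1, 1467 without LD 3, 586 without LD 2, 592 without DMSO 3 and 597 without DMSO 5, and 3499 with HINTW as a covariate, with 0 probes passing each time. No list was called. The cell cycle list came nearest, with a median of 0.15 and 15 of 23 genes above 0 (camera, adjusted p = 0.0615; 0.883 with an estimated correlation). This cell cycle list was called in low dose against DMSO without DMSO 3 (adjusted p = 0.00299), without DMSO 5 (0.0187), without LD 3 (0.000282) and without LD 4 (0.0337). Its members TPX2, a spindle protein, and PLK1, a mitotic kinase, had 0.35 ± 0.18 and 0.21 ± 0.13, and RRM1, which makes deoxyribonucleotides, -0.55 ± 0.31. Immediate early genes had a median of -0.09 over 11 genes (adjusted p = 0.67), with FOS at -0.93 ± 0.28 and JUN at -0.59 ± 0.23. Heat shock proteins had -0.25 over 10 genes (adjusted p = 0.59), with HSPA4L at -0.47 ± 0.27, against a median of -0.10 over all genes tested. The blood list, called at the high dose, had a median of 0.03 and a mean of -0.02 at the low dose, and camera placed it above other genes (adjusted p = 0.80).

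**Figure D4:**
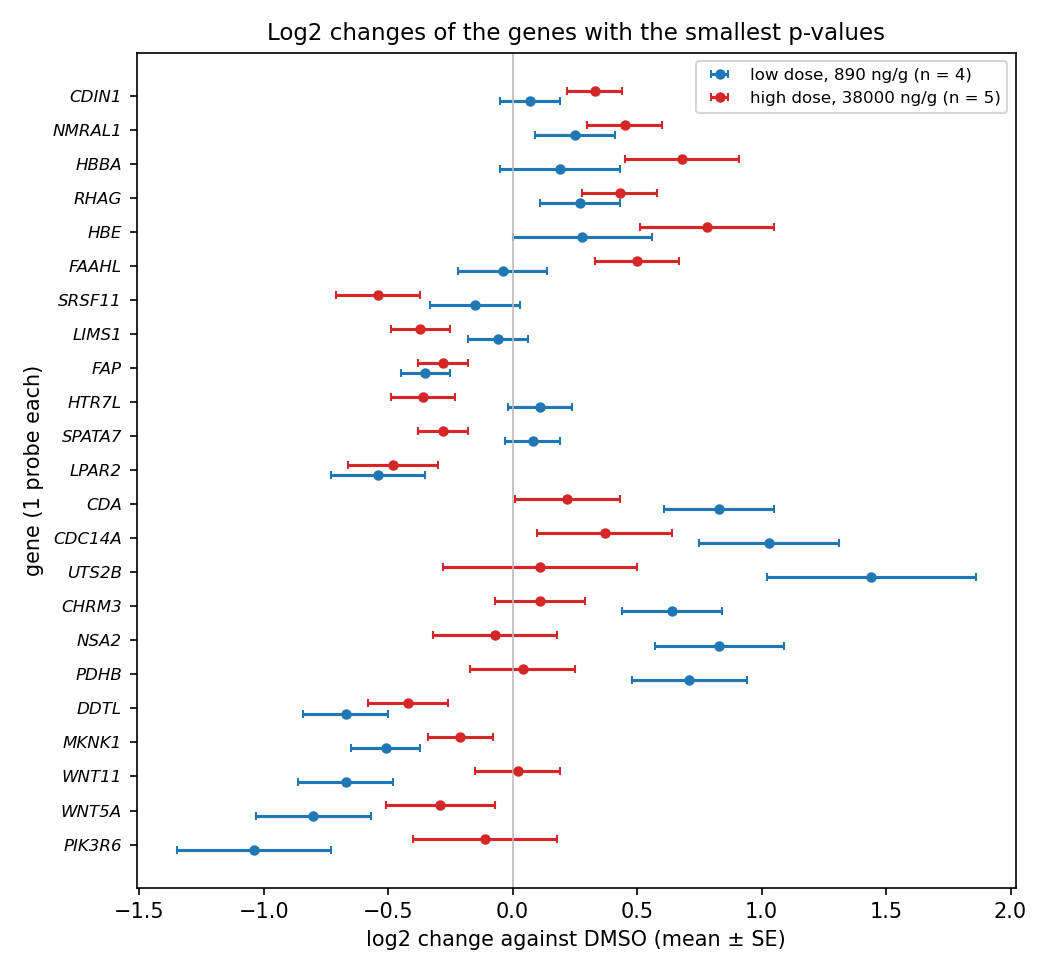
Each line is a gene of smallest unadjusted p in either comparison with DMSO, and points with bars give the log2 change against DMSO with its SE at the low dose (blue) and the high dose (red). The largest value is that of UTS2B at the low dose (1.44 ± 0.42); no gene shown passed the adjusted threshold.

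The doses were then set against each other, which also tests whether their effects differ. VIP, a neuropeptide of interneurons, and its receptor VIPR2 did not pass and had log2 differences of 1.53 ± 0.42 (2.88-fold) and 1.33 ± 0.31 (2.52-fold). VIPR2 was at -1.52 to -0.46 on the LD arrays, -0.09 to 0.75 on the HD arrays and -1.07 to 0.48 on the DMSO arrays, so the low dose lay below DMSO by a difference of -0.73 ± 0.31 and the high dose above it by 0.60 ± 0.29. VIP was low on the low-HINTW arrays DMSO 4 (-1.08), HD 2 (-0.96), LD 3 (-1.89) and LD 4 (-1.20). On LD 1, where HINTW was at -4.00, VIP was at -0.32. Apart from LD 2, the arrays without low HINTW had -0.41 to 0.90. The lowest VIP value, -2.00, was on LD 2, where HINTW was at -0.05. That array was unlike the others in both channels and cannot decide between dose and sex. With HINTW (the W probes) as covariate the differences were 1.17 for VIP and 1.21 for VIPR2, in a fit that includes LD 2. FOS, an immediate early transcription factor, had 1.09 ± 0.28 (2.13-fold), the reelin receptor gene VLDLR 0.83 ± 0.20, CA2, a carbonic anhydrase, 0.76 ± 0.20 and WNT11 0.69 ± 0.19. Lower were NSA2 (-0.89 ± 0.26), the matrix proteoglycan VCAN (-0.76 ± 0.24), TMEM164 (-0.53 ± 0.16), HTR7L (-0.47 ± 0.13) and SPATA7 (-0.36 ± 0.11). TMEM164 had no value on LD 2, and 1 of its 2 other probes had the opposite sign.

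limma called 0 of 30294 probes between the doses (smallest adjusted p = 0.799). Slightly fewer than expected with no change, 1389 (4.59%) had an unadjusted p under 0.05, of which 809 were higher and 580 lower. This count was 2238 without LD 1, 2117 without LD 3 and 2320 without LD 4, and 4176 with HINTW as a covariate. Adjusted over the list alone, FOS among the immediate early genes (adjusted p = 0.0191) and CA2 among the blood genes (adjusted p = 0.0244) passed. FOS was at -1.69 on LD 2, -0.93 on LD 3, -0.82 on LD 4 and -0.07 on LD 1, and CA2 at -0.90 on LD 2, -0.73 on LD 4, 0.00 on LD 3 and -0.13 on LD 1.

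The cell cycle list fell at the high dose against the low dose, with a median of -0.14 and a mean of -0.09 over 23 genes, 16 of them below 0 (camera, adjusted p = 0.0324). The call was lost with an estimated correlation (adjusted p = 0.622 with an estimated correlation), and fry made no call against no change (adjusted p = 0.729). PLK1 had -0.28 ± 0.13, BUB1, a kinase of the spindle checkpoint, -0.31 ± 0.16 and MCM3 -0.31 ± 0.20, whereas MCM6, which like MCM3 belongs to the replicative helicase, had 0.62 ± 0.20. None passed adjusted over the list alone. The differences within slides were -0.53, 0.01, 0.19 and -0.02, and with slide as a block the median was -0.13 (adjusted p = 0.0311). The call was lost without LD 1 (median -0.0753, adjusted p = 0.369), LD 2 (-0.0943, 0.377), HD 1 (-0.0869, 0.128) or HD 5 (-0.103, 0.0971), and the median was -0.286 without LD 3 and -0.217 without LD 4; the adjusted p ranged from 0.000186 to 0.729 over 32 alternatives. The call was also lost with the series matrix (adjusted p = 0.0565) and without the arrays DMSO 5, LD 2 and HD 5 (median -0.0831, adjusted p = 0.588), and the median was -0.0629 with the Cy5 channel alone.

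Other lists were not called between the doses. Blood and red cells had a median of 0.42 over 11 genes (camera, adjusted p = 0.15), with HBE1 at 0.59 ± 0.21 and LMO2 at 0.31 ± 0.13. GABA interneurons and receptors had a median of 0.20 over 13 genes (adjusted p = 0.44). VIP, at its brightest probe, had 1.26 ± 0.42, and the interneuron transcription factors DLX5, DLX6 and DLX1 had 0.76 ± 0.40, 0.54 ± 0.35 and 0.47 ± 0.31. Striatal and monoamine markers had -0.13 over 10 genes (adjusted p = 0.14), with RARB at 0.64 ± 0.26 and MEIS2 at -0.58 ± 0.27. The median over all genes tested was 0.10 in this comparison.

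Over the 3 groups together, limma's F test called 0 of 30294 probes (smallest adjusted p = 0.968). Fewer than expected with no change, 583 (1.92%) had an unadjusted p under 0.05. There were 1305 without LD 1, 883 without LD 4, 914 with slide as a block and 2238 with HINTW as a covariate. The changes at both doses shared the DMSO arrays. Across 30294 probes, which are not independent replicates, their Pearson correlation was 0.258 and their covariance 0.0114. Simulated unchanged groups that shared a control group gave a mean correlation of 0.484 ± 0.265 (SD, 100 simulations, 82 of them at least as high). Their mean covariance was 0.03, from which the observed covariance differed by -0.0186. The simulations shuffled residuals over all arrays, so LD 2, of wide spread, could fall in any group and not only the low dose. They thus cannot decide whether the observed values lie below chance. With the DMSO arrays split so that the doses shared none, the mean correlation over 20 splits was -0.124. With the controls shared, the correlation was 0.487 with median centring in place of loess, 0.134 without DMSO 5, LD 2 and HD 5, 0.403 without DMSO 2, 0.169 without LD 4 and 0.164 without HD 2.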

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

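The tests of embryo sex, of single high-dose embryos and of a dose step for the blood list, and all tests on the arrays LD 2, DMSO 5 and HD 5, were chosen after the results were seen; the counts of other splits of the arrays were planned.

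The blood and red cell list was higher at the high dose by a median of 0.29 with the preset correlation, and was not called with an estimated correlation (adjusted p = 0.497). HINTW was at -4.00 or below on 1 of 5 arrays in each of these groups, so HINTW as a covariate could hardly move this comparison. The median was 0.284 with it (camera, adjusted p = 0.0049), which cannot decide on sex. With any 1 HD array left out, the list stayed called at the preset correlation (camera, adjusted p at most 0.027). This cannot decide on bloody HD embryos, since the list is not called with an estimated correlation even on all arrays. HD 2 and HD 3, which had the highest list means (0.32 and 0.30), were also not left out together. Within slides the high dose lay above DMSO by 0.22, 0.30, 0.52 and 0.12, so the direction did not rest on 1 HD embryo. The call was lost without DMSO 3 (adjusted p = 0.0616) and without DMSO 4 (0.108). Chance cannot be excluded: 5 of 100 splits of the arrays, the real grouping among the 5, gave this list a camera p as small as the real 0.00012. The smallest of the other splits was 1.8e-05. A step with dose cannot be told apart from a difference at the high dose alone, because the low-dose median was 0.03 and high against low dose did not pass in the main fit. High against low dose did pass with the replicate block (camera, adjusted p = 0.041), and within slides it was 0.22, 0.40, 0.28 and 0.41. Low dose against DMSO was 0.00, -0.10, 0.24 and -0.29 there. More blood in the tissue, or a response of blood genes to PFHxS, may each be candidate explanations, and no test here separates them.

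LD 2 stood apart in the SD of its log2 ratios (0.913, others of its group 0.248 to 0.345), its spike-in slope (0.646), the Spearman correlations of its Cy5 signals (0.416) and Cy3 signals (0.795) with other arrays, and HINTW (-0.0499). It also stood apart in its group for VCAN (0.74), the heat shock list (-0.55), the astrocyte and radial glia list (-0.88) and the list of brain regions outside the telencephalon (0.54). RNA of that embryo, by its amount, quality or response to the low dose, is argued against as the whole source, because the pool in the Cy3 channel, the same RNA on every array, ranked probes unlike other arrays (0.795, against at least 0.955). A fault in labelling, hybridisation or washing that touched both channels may be the source: the spike-in correlation was 0.862, narrowly below the lowest of the other arrays at 0.888. The step at fault stays open.

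On DMSO 5 and HD 5 the spike-ins, TTR and HINTW were pulled towards 0, with spike-in slopes of 0.577 and 0.529, but the SDs over probes (0.309 and 0.292) lay within those of the other 11 arrays and PIT54 was still at -2.48 and -1.95. Mixing of RNA before labelling is argued against, since that would leave the spike-ins, added at labelling, unchanged, and the higher of the 2 slopes was 0.577 where other arrays had at least 0.901. A leak of each dye into the other channel, fitted on 10 spike-ins, gave 27.5% and 40.4% of Cy3 signal in Cy5. On the software's own log ratios, without loess, this leak predicted TTR at -2.00 and -1.84 where -1.19 and -0.70 were seen (-1.36 and -1.34 after loess). The largest difference, 1.14, lay only just within the tolerance set, the SD of TTR on other arrays (1.20). That tolerance was too wide, because such a leak would set a floor under the ratio and narrow the spread of TTR. On the spike-ins the root mean square residual of the fit was only 0.163 on DMSO 5 and 0.247 on HD 5. The TTR values thus gave the fitted leak no support. For HINTW the leak gave -1.96 and -1.81 from the lowest ratio on other arrays, and 0.736 and 0.505 from the highest. The HINTW values seen were -1.40 and -0.953, nearer the former. A dim spike-in, E1A_r60_n11, argued the other way on HD 5, at -1.79 where the leak gave -1.16, so the source stays open, and no biological explanation was tested.

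Single arrays stood apart from the rest of their group in further values, with 19 such values among 212 groups tested where chance gives about 10.6, since it marks about 1 in 20 groups; 9 of the 19 were on LD 2. TTR was -5.74 on LD 3 (others of the group -4.48 to -4.23). SRSF11 was 0.49 on DMSO 1, PDHB -0.79 on HD 3, DDTL -0.01 on LD 4, WNT11 -0.55 on DMSO 4 and POU2F1 -0.38 on HD 2. The striatal and monoamine list was -0.24 on HD 3, and the list of choroid plexus, ependyma and meninges was 0.70 on HD 2 (others -0.73 to -0.50). The cell cycle list differed between the doses' effects by a median of -0.14, a call lost with an estimated correlation (adjusted p = 0.622), and the differences within slides were -0.53, 0.01, 0.19 and -0.02.

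The arrays were also split 100 times into groups of the same sizes, with the real grouping included in the 100 and in every count of splits below. A real count of 0 is reached by every split, so the 100 of 100 splits with as many probes passing, in each comparison and in the F test, tell nothing about chance; the highest other counts were 1, 0, 1 and 9. The same holds for the lists called in low dose against DMSO (100 splits, real 0, highest other 10). On the 28898 probes with a value on every array, 299, 877, 1336 and 554 had an unadjusted p under 0.05 in high dose against DMSO, low dose against DMSO, high dose against low dose and the F test, and 79, 83, 55 and 81 splits gave as many. As many lists were called in 57 splits for high dose against DMSO (real 1, highest other 8) and in 71 for high dose against low dose (real 1, highest other 6), so chance was not excluded for these counts. The cell cycle list had a p as small as the real 0.0012 in 24 splits, with 1.8e-09 as the smallest of the others.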

How the results depend on the processing

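Leaving out the 3 arrays with low spike-in slopes, the slide block without LD 2, and the list tests with outlier spots kept were chosen after seeing the data. limma called 0 probes in each comparison under all 34 alternatives (32 for the F test). The counts at an unadjusted p under 0.05 ranged from 105 to 1522 for high dose against DMSO, 254 to 3499 for low dose against DMSO, 825 to 4176 for high dose against low dose and 299 to 2238 for the F test. The highest counts for the low dose (3499 and 4176) came with HINTW as a covariate, which within the low dose also sets LD 2 apart. These counts thus cannot be read as an effect of dose that appears once sex is accounted for. With probes of low signal over background kept, which adds probes to the test, these counts were 541, 1470, 2026 and 980.

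The number of lists called for high dose against DMSO was 1, and 0 with an estimated correlation, 0 with fry, 3 with the series matrix and 2 without the 3 arrays. For low dose against DMSO it was 0, and 1 with the mean of all probes per gene, 2 with the processed signals, 2 with median centring, 2 with the series matrix and 2 with HINTW as a covariate. For high dose against low dose it was 1, and 0 with an estimated correlation, 0 with fry, 2 with the mean of all probes, 5 with median centring, 0 with the series matrix, 0 without the filter, 0 with probes well above background on all 14 arrays, 0 with outlier spots kept and 2 with HINTW as a covariate. Leaving out 1 array gave 0 to 4, 0 to 1 and 0 to 3 lists.

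The blood list in high dose against DMSO kept its direction in all 32 alternatives (0.0705 to 0.378). Its call was lost with an estimated correlation and with fry (median 0.286 in both), where only the test changes and fry tests against no change, and leaving out 1 array gave 0.151 to 0.346. The cell cycle list kept its direction too, and its call was lost with an estimated correlation (-0.139), fry (-0.139), the series matrix (-0.162), no filter (-0.138), the filter on all 14 arrays (-0.125), outlier spots kept (-0.134), without the 3 arrays (-0.0831) and with the slide block without LD 2 (-0.0989). Leaving out 1 array gave -0.286 to -0.0753. The correlation of the doses' changes moved from 0.258 to -0.124 with the DMSO arrays split, which removes the shared controls, and leaving out 1 array gave 0.164 to 0.403. The direction of camera's test reversed for the ribosomal proteins list, low dose against DMSO, with median centring, no loess (median -0.561), and for the ribosomal proteins list, high dose against low dose, there too (0.261); both were uncalled otherwise and called there. Where no reason is given, the cause was not tested.

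Among values of genes and lists that were not called, 1442 of the gene values and 2322 of the list values kept their direction and stayed uncalled, whatever their size. The direction changed for 17 and 261, and 33 list values became called. The labels' replicate numbers did not pair the arrays: same-numbered arrays had a median correlation of 0.049 over 13 pairs, 4 of them above 0.1, and 1 of 14 arrays correlated best with its own number. With the replicate block 0 probes passed in each comparison, and 1, 0 and 3 lists were called; those added were the blood and red cells list, high dose against low dose (median 0.406), and the striatal and monoamine markers list, high dose against low dose (-0.138). Z and W probes were not left out, because the reference used gave no chromosome for probes. No block for scan date was fitted. Each slide had a single scan date, so the slide block also takes up differences between dates.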

Other observations

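The genes in this part were chosen after their values were seen. TTR on HD 2 had a linear ratio to the pool of 14.9, which made up 92.1% of the ratios summed over the 14 arrays. The same array was the highest for OTX2, a transcription factor of the choroid plexus, at 1.21, for the matrix genes MMP2 at 1.72 and MGP at 2.08, for FMOD at 0.45 and for transferrin (TF) at 2.70.

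Genes of plasma proteins and of liver tended to be high or low on the same arrays, a pattern that was not tested. The mean over 11 such genes ran from -1.72 on LD 3 to 1.86 on HD 3, but on LD 2 single genes spread from -2.85 to 1.03. Albumin (ALB) was at 2.13 on HD 3, 1.54 on DMSO 4 and 1.34 on LD 1, and lowest at -2.88 on LD 3 and -2.51 on DMSO 1. PIT54, a haemoglobin-binding plasma protein of birds, was at 2.72, 1.17, 0.83, -3.17 and -3.19 on the same arrays, and the fibrinogen chain gene FGB at 2.13, 1.56, 0.56, -1.69 and -2.35. The neuropeptide genes AVP, CCK and NMB were low together on DMSO 4 (-2.63, -1.45 and -2.15), LD 3 (-2.62, -2.71 and -1.72) and LD 4 (-2.13, -1.89 and -1.79), which all had low HINTW. On the other low-HINTW arrays they were at -0.04, -1.47 and 0.89 (HD 2) and at -0.25, 0.11 and -0.52 (LD 1).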
